A study of Mus musculus with 35 samples.

How the data were processed

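ATAC-seq libraries of 35 samples in 9 groups were compared. Per the labels, each library was made from a pool of 1500 sorted cells with 13 PCR cycles. The authors deposited 1 table of raw read counts, not normalized, for 76018 peaks and all 35 libraries. Per the submitters' processing notes, the tools were Trim Galore 0.3.1, Bowtie 1.0.0, SAMtools, bedtools 2.17.0, deepTools, MACS2 2.0.1 and DiffBind 1.14.6 and the genome build was mm9. The notes used here give no role, order or setting for these tools, so how reads were filtered, shifted to the transposase's position or assigned to peaks is not given in the sources used here. The peaks did not overlap, had a median width of 496.0 bp (55 to 8256 bp) and were the same for all libraries. Positions are written as in the deposited table, whose first base (0 or 1) is not given in the sources used here. Even counts were in excess, with 54.1% to 78.2% of the counts from 10 to 49 in a library being even.

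Groups were taken from the titles of the samples. The tissue label of the E9.5 samples names E8.5, and the day was taken from the title. As labelled, the dissected tissue changes between E9.5 and E10.5, where it cannot be told apart from the day, and not between E8.5 and E9.5. Whether the tissue label of the E9.5 samples is right is not given in the sources used here. The counts of pre-HSC I libraries 2 and 3 were closer than sampling noise allows (chi-square of 0.4662 per degree of freedom, Pearson r 0.975 on log2 CPM), so their mean entered as 1 sample. That left 34 samples.

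Peaks with too few counts were removed with filterByExpr by group, which left 67131 peaks and removed 8887. Counts were scaled with TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in 1 fit of all 34 samples with a mean per group, which has 25 residual degrees of freedom and a common dispersion of 0.147. Peaks were called at a Benjamini-Hochberg adjusted p of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Changes of the HE against EC difference between days were tested as interaction contrasts in the same fit. Lists of called peaks were tested in other libraries with camera from limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. Other software was R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. CPM values are counts scaled by the TMM-adjusted library size, given as mean and SD over libraries.

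The peaks named were chosen by a rule set before the data were examined. In each comparison and direction it takes the 10 peaks with the smallest adjusted p among called peaks with an absolute log2 fold change of at least 1 whose libraries in the compared groups do not overlap in CPM. For the interaction contrasts the condition on overlap was not applied. The text gives the first 3 and the range of the 10. Where a group had no counts at a peak, the fold is a lower bound against 3 counts over the group, and where it had 1 to 3 counts a ratio with an exact 95% counting interval is given. The reads were amplified by PCR and carry no molecular identifiers here, so these bounds and intervals cover at most counting error. They treat each read as independent. Given the excess of even counts, reads may come in pairs, and the intervals would then be too narrow and the bounds too high.

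The total count in peaks set the CPM that a given count stands for. In a library with 456770 counts 3 counts are 6.57 CPM, and in one with 7415315 counts 0.405 CPM. The test was run on simulated counts with the real depths, 1 mean per peak for all groups and 1 spread for all peaks and groups. In each comparison 100 peaks were changed at each fold. Of the peaks changed 4-fold it recovered 38 in E8.5 HE against EC, 37 in E9.5 HE against EC, 16 in pre-HSC I against HE and 22 in pre-HSC II against pre-HSC I. Of those changed 2-fold it recovered 0 in each of these comparisons. Of 67131 simulated peaks 59165 passed the count filter, and among these it called 1, 2, 0 and 5 unchanged ones in the same order. A changed peak removed by the filter counted as not recovered. Spread that differs between peaks or groups was left out. Few peaks were changed, which makes the adjustment for multiple testing stricter than where many peaks differ. These numbers may therefore not hold for the real libraries.

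Alternatives set before the data were examined were RLE size factors, scaling by total counts, cyclic loess offsets, DESeq2, no count filter, a fit of only the groups compared, the replicate number as a block, an estimated correlation in camera, and leaving out each library in turn. Those chosen after seeing the data were thinning every library to 456770 counts, keeping pre-HSC I libraries 2 and 3 apart, leaving out the E9.5 libraries with high counts in a chromosome X peak, leaving out the shallow E10.5 HE or E8.5 libraries, and a fit of only E10.5 HE and EC with a replicate block. The replicate numbers of the titles were checked for pairing by correlating each library's deviations from its group mean. A comparison passed where every same-numbered pair had an r above 0.1. Only E10.5 HE and EC passed, with r from 0.125 to 0.331 in the 4 pairs and 8 of 8 libraries correlating best with their own number. The labels do not say what a number stands for.

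Gene lists and motif searches set out beforehand were not run, since the reference used here is a table of GRCm38.p6 genes and the peaks are on mm9. The peaks were therefore not paired with genes.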

Results

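Chromatin accessibility was profiled by ATAC-seq in mouse embryos along the endothelial-to-hematopoietic transition, the process in which endothelial cells (EC) of the large embryonic arteries become hemogenic endothelium (HE) and then release blood progenitors. ATAC-seq uses a transposase that inserts sequencing adapters into open chromatin, so the read count in a region rises with its accessibility. Each of the 35 libraries came from a pool of 1500 sorted cells of a transgenic line that the labels call 23GFP. EC and HE were sampled at embryonic days E8.5, E9.5 and E10.5, with 4 libraries per population and day. A population labelled pro-HSC/HPC was sampled at E9.5 with 3 libraries, where HSC is hematopoietic stem cell and HPC hematopoietic progenitor cell. Populations labelled pre-HSC I and pre-HSC II were sampled at E10.5 with 4 libraries each. Counts were given for 76018 peaks on build mm9, and peaks are named here by their mm9 position as the files write it, without gene names, since no annotation of that build was used.

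The total count in peaks per library ran from 456770 in pre-HSC II library 1 to 7415315 in E9.5 HE library 1. It lay between 1004036 and 2788837 in E8.5 EC, 1502905 and 5733154 in E8.5 HE, 1170513 and 7283508 in E9.5 EC, 1839721 and 7415315 in E9.5 HE, and 1232426 and 3810683 in pro-HSC/HPC. At E10.5 it lay between 2117133 and 5371760 in EC, 1101787 and 3690523 in HE, 1632752 and 2102252 in pre-HSC I, and 456770 and 1241216 in pre-HSC II. Pre-HSC I libraries 2 and 3 differed by less than sampling noise, with a chi-square of 0.4662 per degree of freedom against 2.68 to 8.80 in the other 50 pairs of libraries within a group, and were counted as 1 sample. The tests below therefore rest on 34 samples. Nothing in the labels says that the pools came from separate litters, so p-values measure the spread between these samples, part of which may be technical. The spread was estimated over all groups in 1 fit. It can be too small for groups whose libraries vary more and too large for those that vary less, so counts with only the groups compared are given beside.

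Each other group correlated least with pre-HSC II, whose libraries were shallow. By median Pearson r on log2 CPM (counts scaled to a common library size) across peaks, these libraries correlated with each other at 0.664, with pre-HSC I at 0.674, with pro-HSC/HPC at 0.667 and with E10.5 EC at 0.590. After thinning every library to 456770 counts, the mean r was 0.717 within pre-HSC II, 0.701 with pre-HSC I and 0.630 with E10.5 EC. Without thinning, E9.5 EC libraries correlated with each other at 0.897 and with E10.5 EC at 0.898. With thinning the mean r was 0.855 and 0.830. The first principal component, with 22.5% of the variance, ordered the E10.5 groups from EC to pre-HSC II, and the second, with 10.1%, had the E8.5 libraries at its low end, at -61.6 or below, where pre-HSC II library 2 also lay, at -61.7. E10.5 HE was divided on the first component, where libraries 1 and 4 lay beside pre-HSC I and libraries 2 and 3 nearer to EC. Counts were also spread more evenly over peaks in some groups, since the tenth of peaks with the highest counts held 49.0% ± 1.73 (SD, n = 4) of counts in pre-HSC II and 50.3% ± 3.22 (SD, n = 4) in E8.5 EC, against 58.1% ± 0.933 (SD, n = 4) in E9.5 EC.

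**Figure D1:**
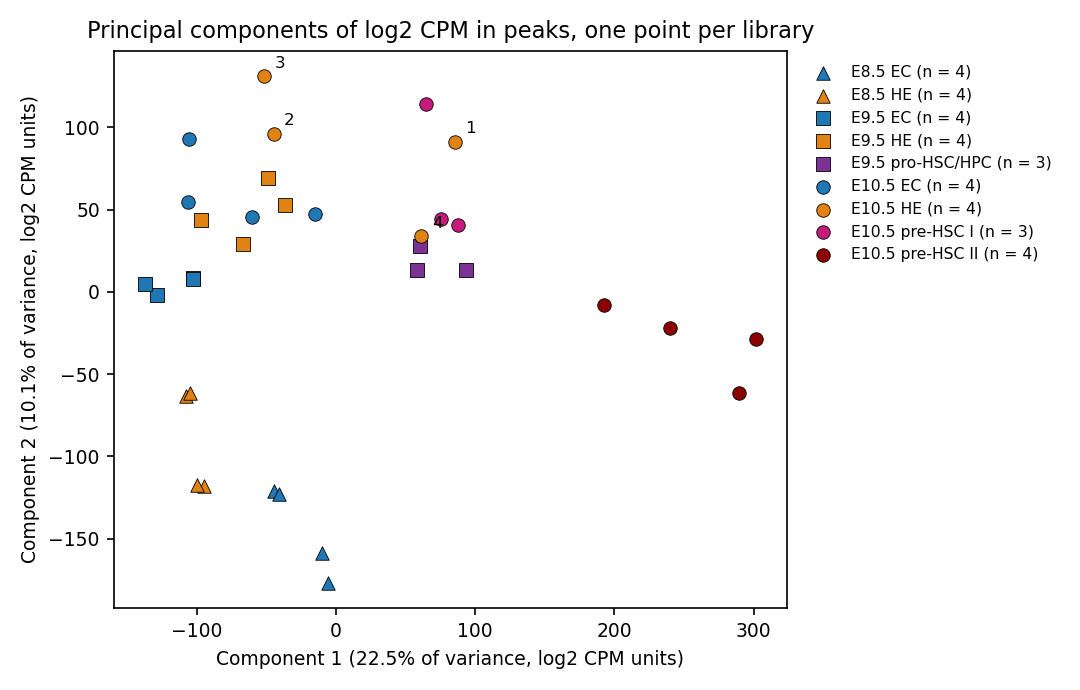
The 34 samples on the first 2 principal components of log2 CPM (22.5% and 10.1% of the variance), 1 point per library, coloured by population and shaped by embryonic day, with the replicate number beside each E10.5 HE library. Pre-HSC II lies at the right end of the first component, and the E8.5 libraries lie at the low end of the second.

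In the 3 comparisons of HE with EC of the same day, the question was which regions open or close as endothelium becomes hemogenic. At E8.5 most regions that differed were more open in HE. Of 67131 peaks tested, 871 were higher and 88 lower in HE than in EC. The peak chr11:106397142-106398275 rose from 4.28 ± 2.03 CPM (SD, n = 4) in EC to 37.8 ± 10.8 CPM (SD, n = 4) in HE, a log2 fold change of 3.10 ± 0.40 (SE). The peaks chr13:41440298-41441870 and chr14:77093255-77094536 rose by 2.83 ± 0.36 and 3.18 ± 0.41 (log2, SE). Among the lower peaks, chr18:65279465-65279634 fell from 32.6 ± 10.9 to 5.09 ± 3.29 CPM (SD, n = 4 each), a log2 fold change of -2.61 ± 0.46 (SE), and chr15:102828384-102830701 and chr13:74880693-74881014 changed by -1.46 ± 0.29 and -4.46 ± 0.89 (log2, SE). Over the 10 leading peaks in each direction the fold ran from 3.92 to 9.09 for higher and from 2.38 to 21.96 for lower peaks. These calls were made with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, and the adjusted p of the 3 higher peaks named was 1.55e-06. The count of 959 changed with the processing: it was 2973 when only these groups entered the fit, 2330 by DESeq2, 282 with every library thinned to 456770 counts, and 17, none of them lower, without the 4 shallow E8.5 libraries (1 and 2 of both populations). Leaving out any 1 of the 8 libraries gave between 437 (without EC library 1) and 660 (without EC library 4).

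At E9.5 HE differed from EC about evenly in both directions, with 912 peaks higher and 821 lower. The peak chr6:141002272-141003297 rose from 8.28 ± 3.85 to 51.8 ± 8.76 CPM (SD, n = 4 each), a log2 fold change of 2.55 ± 0.32 (SE, adjusted p = 2.17e-06 by edgeR). The peaks chr4:82918972-82920268 and chr15:45957002-45957796 rose more steeply, by 3.26 ± 0.42 and 3.42 ± 0.46 (log2, SE). The leading lower peak, chr4:47151715-47152819, fell from 80.1 ± 5.37 to 20.1 ± 4.32 CPM (SD, n = 4 each; log2 fold change -1.98 ± 0.27, SE). The peaks chr3:65662246-65663925 and chr3:144305963-144307266 changed by -1.79 ± 0.27 and -1.56 ± 0.24 (log2, SE). The fold of the 10 leading peaks ran from 3.50 to 13.0 for higher and from 2.94 to 4.92 for lower peaks. The count of 1733 was 6303 with only these groups in the fit, 3021 by DESeq2, 567 after thinning, and between 824 (without HE library 4) and 1191 (without HE library 3) with any 1 library left out. EC libraries 3 and 4 and HE library 4 carried 6470, 7280 and 9126 counts in a single chromosome X peak, chrX:103380576-103383382, and 36 peaks differed without these 3 libraries.

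At E10.5 the balance lay on the side of loss, with 481 peaks higher and 1052 lower in HE than in EC. The same peak led the higher ones as at E9.5: chr6:141002272-141003297 stood at 17.7 ± 6.60 CPM in EC and 74.3 ± 30.4 CPM in HE (SD, n = 4 each; log2 fold change 2.08 ± 0.30, SE, adjusted p = 0.000106 by edgeR). The peaks chr17:89572711-89573478 and chr15:25839597-25840426 rose by 2.48 ± 0.37 and 2.64 ± 0.39 (log2, SE). Among the lower peaks chr11:89839106-89840488 and chr11:110426982-110428254 changed by -1.87 ± 0.28 and -2.13 ± 0.32 (log2, SE). The peak chr9:86270400-86271516 fell from 24.8 ± 1.78 to 5.35 ± 0.796 CPM (SD, n = 4 each), a log2 fold change of -2.22 ± 0.35 (SE). The fold of the 10 leading peaks ran from 3.24 to 10.8 for higher and from 2.85 to 4.66 for lower peaks. With only these groups in the fit the count was 137 without pairing and 2467 (729 higher, 1738 lower) with the replicate number as a block, by which libraries of these groups deviated together. It was 2736 by DESeq2 and 614 after thinning. Without the shallow HE libraries 1 and 4 it was 370, of which 289 were higher, and with any 1 library left out it lay between 582 (without EC library 2) and 2032 (without EC library 1).

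**Figure D2:**
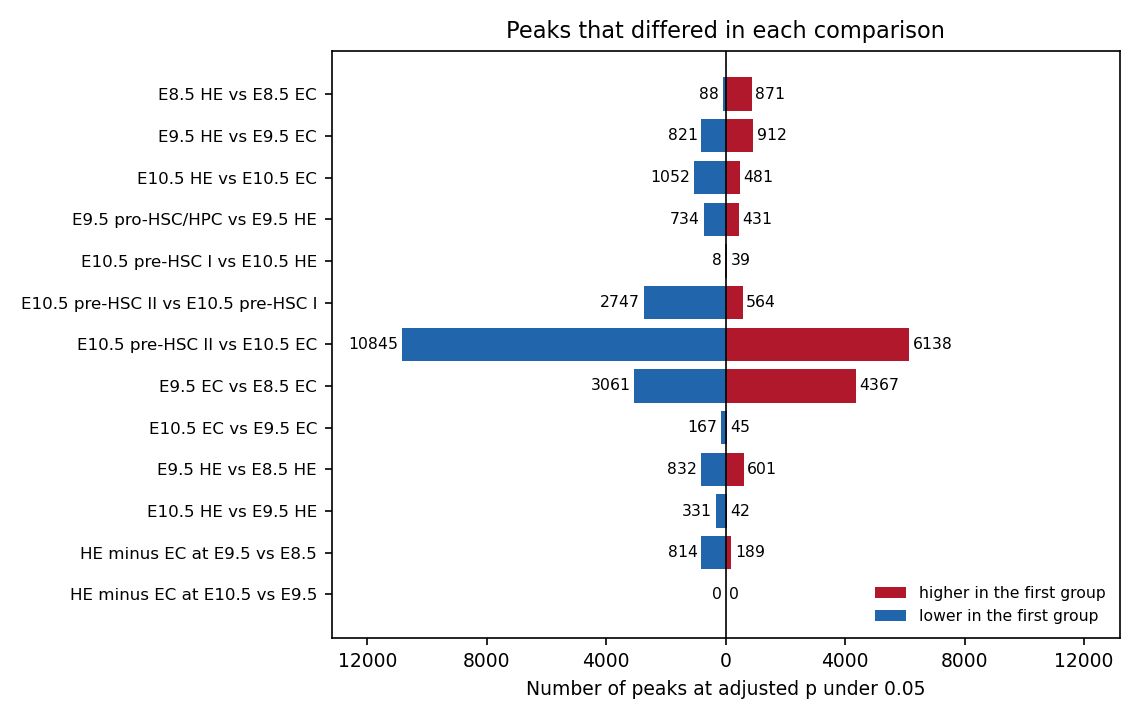
Numbers of peaks at an adjusted p under 0.05 (edgeR) in each of the 13 comparisons, on the horizontal axis, with peaks higher in the first group to the right and lower to the left. E10.5 pre-HSC II against EC has the longest bars (6138 higher, 10845 lower) and E10.5 pre-HSC I against HE the shortest of the comparisons with calls (39 higher, 8 lower).

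The E9.5 and E10.5 differences between HE and EC were called in many of the same peaks and in the same direction. Of the peaks higher in HE at E8.5, some were called at E10.5 in the same and others in the opposite direction. Of the 912 peaks higher in HE at E9.5, 97.5% were also above EC at E10.5, with a median log2 fold change of 1.27, and 259 passed the E10.5 test in the same direction and 0 in the opposite one, where independent lists would share 6.53. Of the 821 lower peaks, 99.1% were lower at E10.5 (median log2 fold change -1.26), and 385 passed the test, where independent lists would share 12.9. The camera set test gave adjusted p = 2.00e-80 and 2.94e-121 for the higher and lower list, and 4.97e-06 and 1.48e-05 with an estimated correlation. Of the 871 peaks higher in HE at E8.5, 119 were also higher in HE at E9.5 (11.8 for independent lists) with a list median of 0.32, and 66.9% had the same sign. That list passed camera at E9.5 (adjusted p = 4.89e-08) but not with an estimated correlation (adjusted p = 0.574), and at E10.5 its median was -0.09 (adjusted p = 0.372), a sign that turned with cyclic loess scaling. At E10.5, 53 of its peaks were called in the same and 52 in the opposite direction, where independent lists would share 6.24 and 13.6. The 88 peaks lower at E8.5 had a median of 0.06 at E9.5 (adjusted p = 0.963) and lay on the higher side at E10.5, with a median of 0.28 (adjusted p = 0.00442, and 0.574 with an estimated correlation). In all, 43 peaks were higher in HE at all 3 days and 0 were lower at all 3, out of 1876 and 1576 called at any day; chr11:24126489-24127811, picked from the 43 after its values were seen, rose by 2.13, 1.83 and 1.69 (log2) at E8.5, E9.5 and E10.5.

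A test of the change in the HE against EC difference from E8.5 to E9.5 gave 1003 peaks, 814 of them with a lower and 189 with a higher difference at E9.5. In the 3 leading peaks of the larger class the mean CPM rose in EC and was lower in HE at E9.5 than at E8.5. The peak chr7:105720479-105722469 went from 36.4 ± 9.13 to 213 ± 5.49 CPM in EC and from 100 ± 9.85 to 98.1 ± 15.3 CPM in HE (SD, n = 4 each), so that the difference changed by -2.55 ± 0.39 (log2, SE; adjusted p = 0.000366 by edgeR). The differences at chr2:135518113-135519379 and chr9:8558439-8559379 changed by -2.43 ± 0.36 and -2.83 ± 0.44 (log2, SE). In the smaller class chr7:133764688-133765548 stood at 2.57 ± 0.918 CPM in E9.5 EC and 19.1 ± 5.72 CPM in E9.5 HE (SD, n = 4 each), and its difference changed by 4.00 ± 0.66 (log2, SE). The differences at chr8:36165054-36165776 and chr5:111964828-111965463 changed by 3.29 ± 0.60 and 3.74 ± 0.72 (log2, SE). The count was 4287 with only these groups in the fit, 2571 by DESeq2, 345 after thinning, 44 without the 3 libraries high on chromosome X and 6 without the shallow E8.5 libraries, and between 437 (without E8.5 EC library 2) and 1088 (without E8.5 EC library 3) with any 1 library left out. From E9.5 to E10.5 edgeR called 0 peaks for a changed HE against EC difference, with 1768 at an unadjusted p under 0.05, and DESeq2 also called 0.

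The E9.5 pro-HSC/HPC population was compared with E9.5 HE to follow the step after the hemogenic stage. It had 431 peaks higher and 734 lower than HE. Among the higher peaks chr2:3575008-3575844 stood at 4.22 ± 2.05 CPM in HE (SD, n = 4) and 41.8 ± 13.1 CPM in pro-HSC/HPC (SD, n = 3), a log2 fold change of 3.33 ± 0.48 (SE, adjusted p = 0.000167 by edgeR), and chr6:119868380-119869063 at 0.537 ± 0.643 (SD, n = 4) and 17.9 ± 5.29 CPM (SD, n = 3; 4.57 ± 0.67, log2, SE). The peak chr10:20774521-20775176 rose by 3.32 ± 0.52 (log2, SE). The lower peaks chr13:84751685-84753250, chr10:74826194-74828242 and chr14:103432162-103433137 changed by -1.92 ± 0.30, -1.68 ± 0.27 and -2.24 ± 0.37 (log2, SE). The fold of the 10 leading peaks ran from 4.84 to 26.1 for higher and from 3.20 to 6.45 for lower peaks. The count of 1165 was 4137 with only these groups in the fit, 2393 by DESeq2, 253 after thinning, 589 without the E9.5 libraries high on chromosome X, and between 361 (without pro-HSC/HPC library 1) and 879 (without HE library 3) with any 1 library left out.

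At E10.5 few peaks separated pre-HSC I from HE at this depth, with 39 higher and 8 lower. At chr19:34919090-34919723 and chr1:177454914-177455363 all HE libraries had 0 counts, and pre-HSC I, with 36 and 52 counts, was at least 19.4-fold and 28.0-fold higher against a floor of 3 counts over the group (adjusted p = 0.00205 and 0.00228 by edgeR). The peak chr5:20446463-20447721 stood at 9.23 ± 4.20 CPM in HE (SD, n = 4) and 42.9 ± 25.1 CPM in pre-HSC I (SD, n = 3), a log2 fold change of 2.12 ± 0.37 (SE). In the other direction chr4:56237450-56237905 and chr4:56265283-56265724 had 0 counts in pre-HSC I and 51 and 43 in HE, at least 10.54-fold and 8.89-fold lower, and chr10:74826194-74828242 fell from 113 ± 35.5 (SD, n = 4) to 48.8 ± 11.1 CPM (SD, n = 3; log2 fold change -1.22 ± 0.26, SE). In simulated data with these depths and 1 spread for all groups, the test recovered 16 of 100 peaks changed 4-fold and 0 of 100 changed 2-fold in this comparison. Most changes of that size were missed there, and the spread and the share of changed peaks in the real groups may differ. The 47 calls became 0 with only these groups in the fit and 0 after thinning, 29 with a replicate block, 244 by DESeq2 (136 higher, 108 lower), 492 with pre-HSC I libraries 2 and 3 kept apart, and 757 (192 higher, 565 lower) without HE libraries 1 and 4. They split into 35 higher and 15 lower with RLE factors and 42 and 16 with loess offsets. With any 1 library left out they lay between 8 (without pre-HSC I library 2) and 124 (without HE library 4). Of the peaks named here all but chr1:177454914-177455363 lost their call without pre-HSC I library 2, which stands for the merged pair. The call at chr4:56265283-56265724 was also lost without HE library 2 or pre-HSC I library 1 or 4, and that at chr10:74826194-74828242 without HE library 2 or 3 or pre-HSC I library 4.

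Between pre-HSC I and pre-HSC II, 2747 peaks were lower and 564 higher in pre-HSC II with TMM scaling. The peak chr17:10582608-10584086 stood at 96.9 ± 31.9 CPM in pre-HSC I (SD, n = 3) and 10.8 ± 4.10 CPM in pre-HSC II (SD, n = 4), a log2 fold change of -3.18 ± 0.35 (SE, adjusted p = 2.03e-08 by edgeR), and chr5:135015442-135016464 and chr8:8801089-8802593 changed by -4.05 ± 0.46 and -3.51 ± 0.41 (log2, SE). Among the higher peaks chr11:113195830-113196352 went from 1.10 ± 1.02 (SD, n = 3) to 32.1 ± 26.7 CPM (SD, n = 4; 4.72 ± 0.84, log2, SE). The peaks chr17:75598832-75599572 and chr4:145174620-145176479 rose by 3.03 ± 0.58 and 1.67 ± 0.32 (log2, SE). The excess of lower peaks depended on scaling: the median log2 fold change of all peaks was -0.16 with TMM and moved up by 0.27, 0.26 and 0.28 with RLE size factors, total counts and cyclic loess offsets, under which the calls split into 898 higher and 1241 lower, 896 and 1320, and 1003 and 968, while DESeq2 gave 1926 and 1684. The count was 953 with only these groups in the fit (559 higher, 394 lower), 1239 after thinning (570 and 669), 5028 with pre-HSC I libraries 2 and 3 kept apart, and between 1284 (without pre-HSC I library 1) and 4487 (without pre-HSC II library 4) with any 1 library left out.

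The ends of the series at E10.5, pre-HSC II and EC, differed at 16983 peaks, 25.3% of those tested. The peak chr14:115345130-115346137 went from 0.819 ± 0.489 CPM in EC to 69.8 ± 29.4 CPM in pre-HSC II (SD, n = 4 each), a log2 fold change of 6.39 ± 0.53 (SE, adjusted p = 1.12e-13 by edgeR). At chr9:99082498-99083249 and chr6:119868380-119869063 all EC libraries had 0 counts, against 163 and 119 in pre-HSC II. Against a floor of 3 counts over the group, pre-HSC II was at least 215-fold and 157-fold higher, with reads taken as independent. Both peaks were already present in pro-HSC/HPC, at 35.5 ± 7.48 and 17.9 ± 5.29 CPM (SD, n = 3 each). The peaks chr10:74826194-74828242, chr3:115411497-115413161 and chr17:10582608-10584086 stood between 123 and 167 CPM in EC and changed by -3.63 ± 0.30, -3.90 ± 0.33 and -3.76 ± 0.33 (log2, SE) in pre-HSC II. With TMM 6138 peaks were higher and 10845 lower, but the other scalings moved the median of all peaks up by 0.27 (RLE), 0.35 (total counts) and 0.24 (loess) and gave 8325 higher and 7693 lower, 9050 and 6889, and 8434 and 6770, and DESeq2 gave 10200 and 8098 (median up by 0.29). The total was 9175 with only these groups in the fit and 6032 after thinning.

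**Figure D3:**
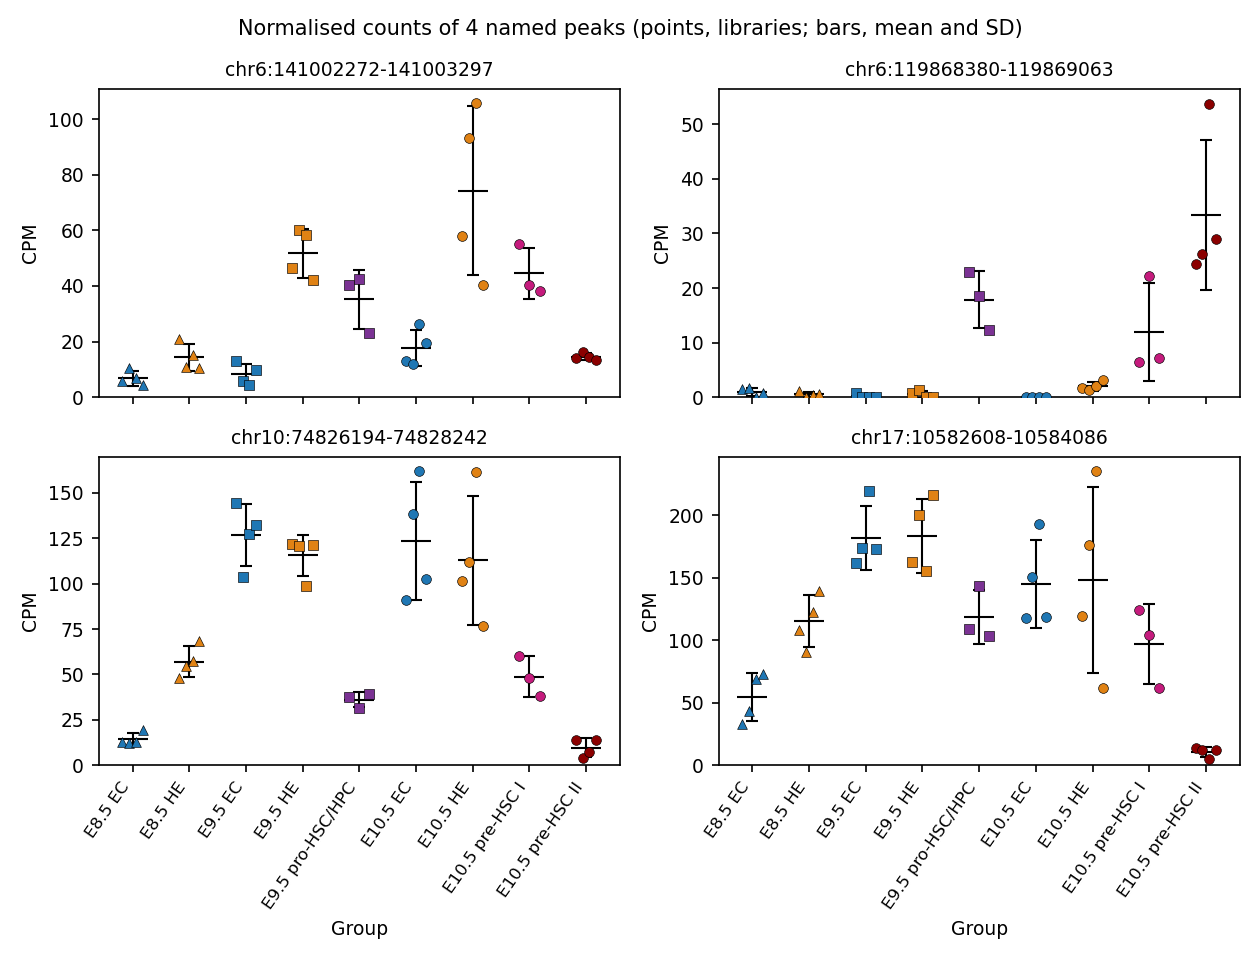
Normalised counts (CPM, vertical axes) of 4 named peaks in the 9 groups, with points for libraries and bars for the mean and SD. At chr6:119868380-119869063 pro-HSC/HPC, pre-HSC I and pre-HSC II stand above EC and HE of every day, and at chr10:74826194-74828242 E8.5 EC (14.3 CPM) and pre-HSC II (9.75 CPM) stand lowest.

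The peaks that set HE apart from EC at E9.5 were followed through the E10.5 populations. The median CPM of the 912 higher peaks was 5.00 in E10.5 EC, 12.6 in HE, 12.3 in pre-HSC I and 7.14 in pre-HSC II, and that of the 821 lower peaks was 28.0, 11.4, 9.27 and 5.74. From HE to pre-HSC I the higher list had a median log2 fold change of -0.15 (camera adjusted p = 0.263) and the lower list one of -0.28 (adjusted p = 4.96e-05, and 0.421 with an estimated correlation). From pre-HSC I to pre-HSC II both lists fell, by medians of -0.74 and -0.59 (adjusted p = 1.70e-10 and 4.96e-05), against a median of -0.16 in all other peaks. Neither passed with an estimated correlation (adjusted p = 0.0594 and 0.421). With cyclic loess offsets the medians were -0.50 and -0.24 (adjusted p = 3.15e-11 and 0.00370), against 0.12 in all other peaks. By the test of single peaks, 184 of the 912 were lower and 4 higher in pre-HSC II than in pre-HSC I, and 128 and 18 with loess offsets. Of the 821, 88 were lower and 12 higher, and 37 and 25 with loess offsets.

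**Figure D4:**
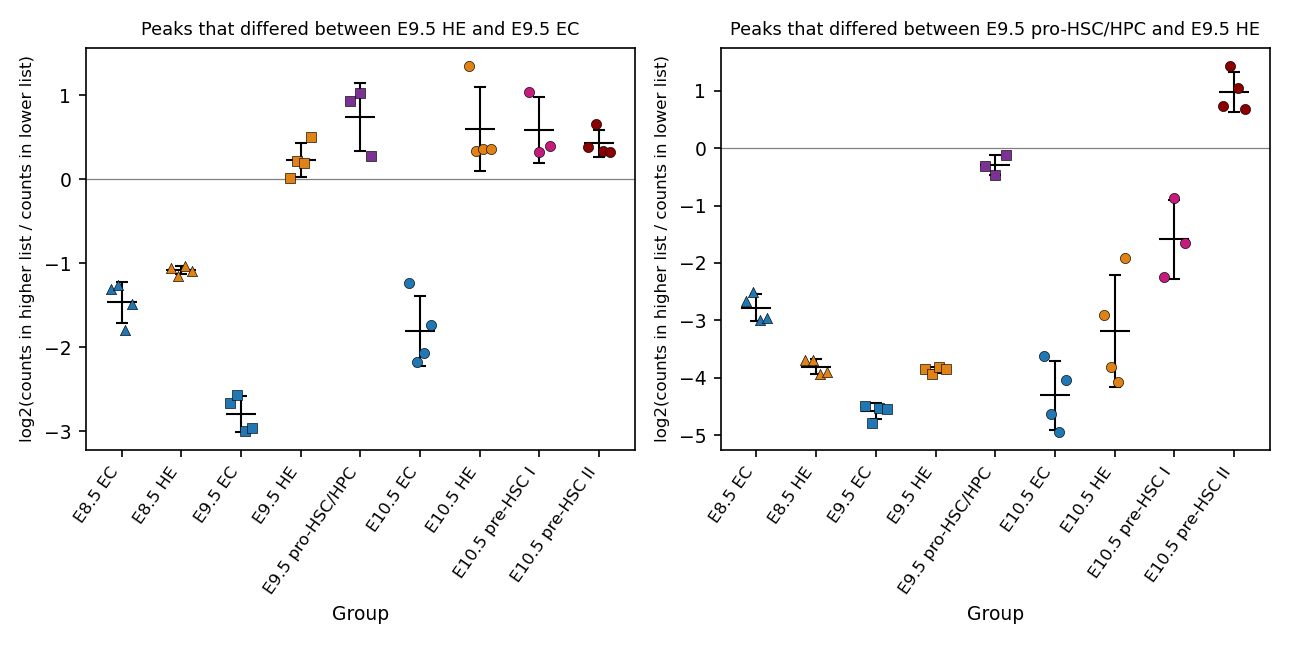
The log2 ratio of counts in the peaks higher to counts in the peaks lower in an E9.5 comparison (vertical axes), with points for libraries and bars for the mean and SD of each group, for HE against EC (left) and pro-HSC/HPC against HE (right). The left ratio is 0.60 in E10.5 HE and -1.80 in E10.5 EC, and the right ratio is -3.18 in E10.5 HE, -1.59 in pre-HSC I and 0.97 in pre-HSC II; the groups that chose each list are drawn too and are not independent of it.

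Between days, more peaks passed the test in EC than in HE from E8.5 to E9.5, and fewer passed in both from E9.5 to E10.5. The labels give the dissected tissue as E8.5 PAS+VU for the E8.5 and also the E9.5 samples and as E10.5 AGM+VU at E10.5. As labelled, day and tissue therefore change together from E9.5 to E10.5 and cannot be told apart there. From E8.5 to E9.5 the tissue label stays the same, but it names E8.5 for samples titled E9.5, so whether the tissue was the same is not settled. In EC, 4367 peaks were higher and 3061 lower at E9.5 than at E8.5. The peak chr10:74826194-74828242 rose from 14.3 ± 3.24 to 127 ± 17.1 CPM (SD, n = 4 each; log2 fold change 3.12 ± 0.26, SE, adjusted p = 5.26e-13 by edgeR). The peaks chr17:84384491-84385937 and chr5:46317016-46317906 rose by 3.31 ± 0.37 and 2.57 ± 0.29 (log2, SE). The peak chr8:36165054-36165776 fell from 45.2 ± 2.53 to 2.14 ± 0.877 CPM (SD, n = 4 each; -4.37 ± 0.47, log2, SE). The peaks chr2:137697945-137698795 and chr1:100206312-100207070 changed by -5.46 ± 0.64 and -3.60 ± 0.45 (log2, SE). Scaling by total counts turned the balance, to 2883 higher and 4790 lower, as it moved the median of all peaks by -0.23. The count of 7428 was 12054 with only these groups in the fit, 2626 after thinning, 1527 without the shallow E8.5 libraries and 3160 without the libraries high on chromosome X, and between 4688 (without E8.5 EC library 2) and 6847 (without E8.5 EC library 3) with any 1 library left out.

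In HE, 601 peaks were higher and 832 lower at E9.5 than at E8.5, led by chr10:105197187-105198064, which rose from 4.64 ± 1.55 to 37.8 ± 9.11 CPM, and chr12:92921856-92923535, which fell from 54.4 ± 8.34 to 11.8 ± 1.46 CPM (SD, n = 4 each; log2 fold changes 2.91 ± 0.42 and -2.17 ± 0.30, SE; adjusted p = 2.36e-05 and 8.89e-06 by edgeR). The peaks chr11:90419707-90420548 and chr1:88366722-88368175 rose by 2.61 ± 0.39 and 2.53 ± 0.38 (log2, SE). The peaks chr1:67368314-67369071 and chr9:85483056-85484120 changed by -3.64 ± 0.50 and -2.85 ± 0.39 (log2, SE). Of the peaks that differed in HE, 187 of the higher and 247 of the lower also differed in EC in the same direction, where independent lists would share 39.1 and 37.9. With RLE factors, which moved the median of all peaks by -0.10, 593 peaks were higher and 1348 lower, and with DESeq2 1062 and 2426. The count of 1433 was 7106 with only these groups in the fit, 727 after thinning, 101 without the shallow E8.5 libraries and 336 without the libraries high on chromosome X. With any 1 library left out it lay between 430 (without E9.5 HE library 4) and 1006 (without E8.5 HE library 3).

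From E9.5 to E10.5 closing regions outnumbered opening ones in both populations. In EC 45 peaks were higher and 167 lower, and in HE 42 and 331. In EC chr1:71982882-71983946 fell from 37.5 ± 4.55 to 5.73 ± 3.30 CPM (SD, n = 4 each; log2 fold change -2.68 ± 0.35, SE, adjusted p = 9.80e-06 by edgeR), chr8:123343615-123344674 and chr13:89635792-89637075 changed by -2.49 ± 0.37 and -1.69 ± 0.26 (log2, SE). The peaks chr15:17065291-17066027 and chr9:8487712-8488198 rose by 2.62 ± 0.49 and 3.97 ± 0.77 (log2, SE). At chr13:102395796-102396264 the E9.5 EC libraries held 2 counts and those of E10.5 56, a ratio of 31.2. Its 95% counting interval, 8.23 to 264, treats reads as independent and may be too narrow. The call of that peak was lost without E9.5 EC library 1 or 2, and that of chr9:8487712-8488198 without E9.5 EC library 2 or E10.5 EC library 1. In HE chr9:86270400-86271516 fell from 32.2 ± 6.25 to 5.35 ± 0.796 CPM (SD, n = 4 each; -2.60 ± 0.34, log2, SE, adjusted p = 7.13e-06 by edgeR), chr11:110426982-110428254 and chr7:6831837-6833234 changed by -2.44 ± 0.32 and -1.80 ± 0.25 (log2, SE). The peaks chr13:78622492-78623149 and chr1:164147282-164148440 rose by 2.63 ± 0.52 and 2.19 ± 0.43 (log2, SE). The peak chr12:37652825-37653257 rose from 3.05 ± 1.65 to 15.4 ± 6.82 CPM (SD, n = 4 each), and its call was lost without E9.5 HE library 4 or E10.5 HE library 4. The EC count of 212 was 1208 with only these groups in the fit, 894 by DESeq2, 79 after thinning and 59 without the libraries high on chromosome X, and between 68 and 175 (without E10.5 EC library 1 or 2) with any 1 left out. The HE count of 373 was 101, 1358, 180 and 221 in the same order, 560 with a replicate block, 35 without the shallow HE libraries 1 and 4, split into 107 higher and 377 lower with loess offsets and 308 and 1050 by DESeq2, and between 111 (without E9.5 HE library 2) and 856 (without E10.5 HE library 3) with any 1 left out.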

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

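Of the tests in this part, those on depth and on trends with peak height were chosen only after the result was seen. In groups of 4 libraries, 1 library stood far from the others in 1 of 21 sets of library values and in 6 of 133 sets of values at named peaks, and chance gives about 1 in 20. E10.5 EC library 1 had a mean correlation of 0.860 with its own group, and the others had 0.899 to 0.904. At chr10:74826194-74828242, E9.5 HE library 3 stood at 98.7 CPM (others 120.6 to 121.8) and E8.5 EC library 4 at 19.1 CPM (others 12.2 to 13.0). At chr6:119868380-119869063 pre-HSC II library 3 stood at 53.7 CPM and the others between 24.4 and 29.0. At chr9:8558439-8559379 E9.5 EC library 3 stood at 106.1 CPM and the others between 64.7 and 68.2. At chr9:8487712-8488198 E10.5 EC library 1 stood at 16.03 CPM and the others between 3.52 and 5.19, so the higher mean of E10.5 EC rests in large part on it. At chr13:102395796-102396264 E9.5 EC library 4 held the counts of its group, 0.704 CPM, and the others had 0.

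The difference between HE and EC itself differed between E8.5 and E9.5, in the interaction test, at 1003 peaks. The change of the difference was -2.43 at chr2:135518113-135519379, -2.55 at chr7:105720479-105722469, -2.83 at chr9:8558439-8559379, 4.00 at chr7:133764688-133765548, 3.29 at chr8:36165054-36165776 and 3.74 at chr5:111964828-111965463 (log2).

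More peaks differed between E9.5 and E8.5 in EC (7428) than in HE (1433), 5.18 times as many, a ratio that ran from 1.70 (12054 and 7106 with only the groups compared) to 15.1 (1527 and 101 without the shallow E8.5 libraries) over the other settings, leaving out single libraries aside. These counts argue against unequal total counts alone or a trend with peak height alone as the cause. The EC count was 3.61 times the HE count after thinning all libraries to 1 total and 3.95 times with loess offsets. Both settings kept the spread estimated over all groups. With only the groups compared the ratio was 1.70, so its size also depends on which groups enter the fit. Thinning does not remove other traits that shallow libraries may share. Thinned E8.5 EC libraries 1 and 2 still correlated less with E9.5 EC (0.736 and 0.716) than libraries 3 and 4 (0.792 and 0.783). E8.5 HE libraries 1 and 2 (0.775 and 0.780) also lay below HE libraries 3 and 4. A cause tied to depth therefore stays open. In thinned libraries E8.5 EC correlated with E9.5 EC at 0.757 ± 0.037 and E8.5 HE at 0.802 ± 0.029 (SD, n = 4 each; two-sided exact permutation p = 0.171). The bound set beforehand, a p of 0.05 or more, was wrongly chosen, since a low correlation between E8.5 and E9.5 EC restates the many differing peaks in the same libraries and decides nothing about their cause. A biological difference between the days was not tested and stays open.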

How the results depend on the processing

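The settings with thinned libraries, with pre-HSC I libraries 2 and 3 kept apart, without the libraries high in a chromosome X peak, without the shallow E8.5 or E10.5 HE libraries, and with only E10.5 HE and EC in a blocked fit were chosen after seeing the data. Scaling by total counts and dropping the count filter kept all 13 counts of called peaks within 1.5 times their value. RLE factors and loess offsets each did so for 12 of 13, and gave 2139 and 1971 peaks for pre-HSC II against pre-HSC I. The replicate block kept 11 of 13 and gave 29 peaks for pre-HSC I against HE and 560 for E10.5 against E9.5 HE. Apart from E10.5 HE and EC, no comparison passed the check for pairing. Libraries correlating best with their own number were 6 of 6 in pro-HSC/HPC against HE and 5 of 6 in pre-HSC I against HE. They were 6 of 8 in E9.5 HE against EC and 0 of 8 in E9.5 against E8.5 EC. These are hints from the data and not from the design. For E10.5 HE against EC a fit of only these groups with the block gave 2467. Keeping pre-HSC I libraries 2 and 3 apart gave 492 peaks against HE and 5028 for pre-HSC II against pre-HSC I. DESeq2 gave more calls in 9 comparisons: 2330, 3021 and 2736 for HE against EC at E8.5, E9.5 and E10.5, 2393 for pro-HSC/HPC against HE, 244 for pre-HSC I against HE, 894 for E10.5 against E9.5 EC, 3488 for E9.5 against E8.5 HE, 1358 for E10.5 against E9.5 HE and 2571 for the HE against EC difference at E9.5 against E8.5. The cause was not tested.

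With only the groups compared in the fit, which estimates the spread from fewer samples, the counts were 2973, 6303 and 137 for HE against EC at E8.5, E9.5 and E10.5, 4137 for pro-HSC/HPC against HE, 0 for pre-HSC I against HE (244 by DESeq2, 5483 at an unadjusted p under 0.05 by edgeR with all groups), 953 for pre-HSC II against pre-HSC I and 9175 against EC, 12054 and 1208 for EC between consecutive days, 7106 and 101 for HE, and 4287 for the difference at E9.5 against E8.5. Thinning every library to 456770 counts, which lowers the depth, gave 282, 567 and 614 for HE against EC, 253 for pro-HSC/HPC against HE, 0 for pre-HSC I against HE, 1239 and 6032 for pre-HSC II against pre-HSC I and EC, 2626 and 79 for EC between days, 727 and 180 for HE, and 345 for the difference. Leaving libraries out also lowers the number of samples. Without the libraries high on chromosome X the counts were 36 for E9.5 HE against EC, 589 for pro-HSC/HPC against HE, 3160 and 59 for EC between days, 336 and 221 for HE, and 44 for the difference. Without the shallow E10.5 HE libraries they were 370 for HE against EC, 757 for pre-HSC I against HE and 35 for E10.5 against E9.5 HE. Without the shallow E8.5 libraries they were 17 for HE against EC, 1527 for EC and 101 for HE at E9.5 against E8.5, and 6 for the difference. The change of the HE against EC difference from E9.5 to E10.5 gave 0 calls in every setting run.

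Leaving out 1 library moved most counts by over 1.5 times. E8.5 HE against EC gave 437, 444 and 487 without EC libraries 1 to 3 and 635, 597, 477 and 574 without HE libraries 1 to 4, in a range of 437 to 660. E9.5 HE against EC gave 988, 1074, 1140 and 976 without EC libraries 1 to 4 and 1090, 1085 and 824 without HE libraries 1, 2 and 4 (824 to 1191). E10.5 HE against EC gave 582 and 762 without EC libraries 2 and 3 and 718 and 943 without HE libraries 1 and 4 (582 to 2032). Pro-HSC/HPC against HE gave 565, 367 and 759 without HE libraries 1, 2 and 4 and 361, 458 and 425 without pro-HSC/HPC libraries 1 to 3 (361 to 879). Pre-HSC I against HE gave 14, 13 and 124 without HE libraries 2, 3 and 4 and 114, 8 and 71 without pre-HSC I libraries 1, 2 and 4, where library 2 stands for the merged pair (8 to 124). Pre-HSC II against pre-HSC I gave 1284 without pre-HSC I library 1 and 1681 without pre-HSC II library 2 (1284 to 4487), and against EC no library moved the count so far (13194 to 18442). E9.5 against E8.5 EC gave 4716 and 4688 without E8.5 EC libraries 1 and 2 (4688 to 6847). E10.5 against E9.5 EC gave 80, 71, 135 and 123 without E9.5 libraries 1 to 4 and 68 and 95 without E10.5 libraries 1 and 4 (68 to 175). E9.5 against E8.5 HE gave 547 and 519 without E8.5 libraries 1 and 2 and 829, 774, 696 and 430 without E9.5 libraries 1 to 4 (430 to 1006). E10.5 against E9.5 HE gave 167 and 111 without E9.5 libraries 1 and 2 and 116, 663 and 856 without E10.5 libraries 1, 2 and 3 (111 to 856). The difference at E9.5 against E8.5 gave 484 and 437 without E8.5 EC libraries 1 and 2, 630 and 563 without E8.5 HE libraries 1 and 2, 665 and 627 without E9.5 EC libraries 1 and 2, and 530 and 467 without E9.5 HE libraries 3 and 4 (437 to 1088). That from E9.5 to E10.5 stayed at 0.

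Of the list tests, 5 lost their call with an estimated correlation: the E8.5 higher list at E9.5 and the E8.5 lower list at E10.5 (adjusted p = 0.574 each), and the E9.5 lower list in pre-HSC I against HE (0.421) and both E9.5 lists in pre-HSC II against pre-HSC I (0.0594 and 0.421). The block changed no call of a list. The first 3 peaks given per comparison and direction are 63 distinct peaks in 72 tests, since 7 of them appear more than once. The other peaks behind the ranges of the leading 10 were not followed through these settings. All 72 tests kept their call under RLE factors, total counts, loess offsets, no filter and libraries kept apart. It was kept in 71 under DESeq2, 71 with the block, 63 with only the groups compared and 57 after thinning. Of the tests whose groups hold the libraries left out, 18 of 24 kept it without the shallow E8.5 libraries, 40 of 42 without those high on chromosome X (with 1 more loss in the 30 other tests) and 16 of 18 without the shallow E10.5 HE libraries. With 1 library of the compared groups left out, 589 of 606 repeats kept it and 17 did not. None changed direction in these settings. Gene lists, motifs and their alternatives were not run.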

Other observations

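Of the tests in this part, those of scaling and depth in pre-HSC II and of a day or batch shared by same-numbered libraries were chosen only after the result was seen. The peaks that set pro-HSC/HPC apart from HE at E9.5 moved the same way, as lists of peaks, in both pre-HSC populations. The median CPM of the 431 higher peaks was 2.54 in E10.5 HE, 8.28 in pre-HSC I and 20.9 in pre-HSC II, and that of the 734 lower peaks was 19.4, 12.9 and 5.07. Against E10.5 HE the higher list had a median log2 fold change of 1.63 in pre-HSC I and 3.02 in pre-HSC II, with 96.1% and 98.1% of its peaks above HE (camera adjusted p = 6.25e-68 and 1.26e-97, and 5.59e-05 and 2.31e-06 with an estimated correlation). The lower list had medians of -0.56 and -1.95 (adjusted p = 1.05e-22 and 4.36e-60, and 0.0358 and 0.00231 with an estimated correlation). Of the 431 higher peaks, 390 were also higher in pre-HSC II than in E10.5 EC, and of the 734 lower ones 642 were lower, where independent lists would share 39.4 and 119. Single peaks of the lists were called in the same and the opposite direction 349 and 0 times (higher) and 521 and 1 times (lower) in pre-HSC II against HE, but 26 and 0 and 1 and 1 times in pre-HSC I against HE. By library, the log2 ratio of the lists differed from HE with an exact two-sided permutation p of 0.0286, the smallest the design allows (adjusted p = 0.0571), in pre-HSC II. In pre-HSC I the p was 0.0857 (adjusted p = 0.114), with HE library 4 (-1.92) above pre-HSC I library 1 (-2.25), so a shift there was not shown library by library.

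In both comparisons examined, the nearest tested peak of a called peak was called in the same direction more often than in shuffles, though for most called peaks it was not. Of the peaks that differed between pre-HSC II and EC at E10.5, 23.8% had a nearest tested peak called in the same direction, and the highest of 1000 shuffles within classes of mean count gave 14.9%. Of those that differed between E9.5 and E8.5 EC the share was 15.4%, and the highest shuffle gave 7.04%.

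With TMM scaling more peaks were lower than higher in pre-HSC II against pre-HSC I (2747 and 564). Both technical explanations stay open. With loess offsets, which remove trends with peak height, 50.9% of calls were higher, and with all libraries thinned to 1 total 46.0% were, so that unequal spread of counts over peaks or unequal depth may account for the excess. No biological explanation was tested.

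E10.5 HE libraries 1 and 4 lay near pre-HSC I and libraries 2 and 3 near EC on the first component. Libraries 1 and 4 were the shallow ones, with 1215458 and 1101787 counts against 3115691 and 3690523 in 2 and 3. The tables argue against unequal total counts alone, since in thinned libraries 1 and 4 (53.0 and 46.7) still lay above 2 and 3 (-25.0 and -31.1), by at least 71.7. Thinning does not remove other traits that shallow libraries may share, so a cause tied to depth stays open. More blood progenitor signal in libraries 1 and 4 may account for it, but the ratio used here cannot decide this. The log2 ratio of the pro-HSC/HPC lists was -2.91 and -1.92 there. In libraries 2 and 3 it was -3.82 and -4.08, a gap of at least 0.90. The ratio was also higher in EC libraries 1 and 4 (-3.62 and -4.03) than in EC libraries 2 and 3 (-4.63 and -4.95). It is therefore not specific to HE. Its mean in E8.5 EC, -2.78, was above that in E8.5 HE, -3.81, so a higher ratio need not mean more progenitor signal. Whether the ratio follows how evenly counts spread over peaks was not tested. A day or batch shared by same-numbered libraries may account for it too, since EC libraries 1 and 4 (-3.49 and -37.5) also lay above EC libraries 2 and 3 (-66.9 and -68.6), by at least 29.4. EC libraries 1 and 4 were also shallower, with 2117133 and 3620001 counts against 5371760 and 4283412 in EC libraries 2 and 3. These explanations were not told from each other.

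Other splits of the same libraries were refitted for each count of called peaks. Of 35 splits only the real one gave as many for E8.5 HE against EC (959, highest other 17) and E9.5 HE against EC (1733, highest other 1). So it was for pro-HSC/HPC against HE (1165, highest other 6) and pre-HSC II against EC (16983, highest other 2998). It was also so for E9.5 against E8.5 EC (7428, highest other 1) and E10.5 against E9.5 EC (212, highest other 3). In HE it was so for E9.5 against E8.5 (1433, highest other 0) and E10.5 against E9.5 (373, highest other 0). These counts argue against chance, but 35 splits cannot exclude it, and no adjustment was made over the comparisons. For pre-HSC II against pre-HSC I the real split also gave the most (3311). The highest other, with pre-HSC II library 4 placed among pre-HSC I, gave 2921, so the real grouping stood little apart. That other split followed depth, with 1241216 counts or more in each library placed with pre-HSC I and 701221 or less in the rest. For the HE against EC difference at E9.5 against E8.5, 40 splits were drawn, and the real one gave 1003 and the highest other 16. The other splits mix HE and EC within a day and so remove the difference itself. They cannot say whether its change between the days is due to chance.

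Chance cannot be excluded for E10.5 HE against EC by the count of splits, since 2 of 35 gave as many as 1533. The other grouped EC library 1 with HE libraries 1, 2 and 4 and gave 2026. Each of these had a lower total count (3115691 or less) than each of the rest (3620001 or more). A split that followed depth therefore gave more calls than HE against EC. Among the 7 other splits that part all 4 same-numbered pairs, as the real one does, the highest gave 5. The E9.5 lists of HE against EC, chosen in other libraries, argue against chance for the peaks they hold. At E10.5, 97.5% of the higher and 99.1% of the lower peaks kept their sign, and 259 and 385 were called, 0 in the opposite direction. Camera with an estimated correlation gave adjusted p = 4.97e-06 and 1.48e-05. The log2 ratio of these lists was 0.334 to 1.35 in E10.5 HE libraries and -2.18 to -1.24 in EC. For pre-HSC I against HE 9 of 35 splits gave 47 or more. The highest, HE libraries 2 and 3 with the merged pre-HSC I library 2 against the rest, gave 1292. Each of these libraries had a higher total count (2.10e+06 or more) than each of the rest (1.64e+06 or less). That split therefore followed depth rather than the groups. Depth itself was not told apart from other traits of these libraries. For the difference at E10.5 against E9.5 the real count was 0 (1768 at an unadjusted p under 0.05 by edgeR, 0 by DESeq2). With 0 calls any split gives as many, so that the 40 of 40 splits say nothing about chance. The highest other gave 3622, and since such splits mix HE and EC within a day, what it reflects was not tested.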
